A study of Homo sapiens with 6 samples.

How the data were processed

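RNA from 6 subcutaneous tumours of 1 human pancreatic cancer cell line, grown in nude mice, was sequenced, 4 off and 2 on doxycycline. Per the labels' protocols, total RNA was extracted with Trizol and libraries followed standard Illumina protocols. The authors deposited a table of whole-number counts per gene for the 6 tumours. Per the submitters' processing notes, STAR, HTSeq and limma were used with the human build hg19; their roles, versions and settings, the annotation release, the strand setting and the handling of mouse reads are not given in the sources used here. Reads from host cells that align to human genes can therefore be part of the counts, and a gene and an overlapping antisense gene cannot be told apart. No tumour with a control hairpin is part of the design, so doxycycline, the induction of a hairpin and any effect of lower ME3 coincide.

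The table held 57798 lines, of which 25 with a repeated identifier were removed, leaving 57773 genes. A symbol was missing for 24323 genes, and 18931 of these were named from a GENCODE annotation by identifier; 27 symbols had been turned into dates and were restored in the same way. That annotation is on another build than the files, so it was used only for names, gene types and transcript sequence, and no coordinates are given. Groups were taken from the sample labels. Library totals were 23855338 to 26885699 counts. No pair of tumours was a duplicate: the chi-square statistic per degree of freedom between tumours of a group was 9.65 to 21.8 off dox and 52.7 on dox.

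Genes were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with TMM factors, the default filterByExpr filter (21308 genes kept, with at least 99.85% of each tumour's counts) and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are on dox minus off dox. CPM values use TMM-scaled library sizes, and their SD is over tumours. The common dispersion was 0.0353, a biological coefficient of variation of 18.8%. Single genes fixed in advance were also tested with a two-sided exact permutation test over the 15 splits of the tumours into 4 and 2, which cannot give a p under 0.0667.

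Before the data were examined, 37 gene lists were written, covering metabolic and stress pathways, host cell types and RNA quality. Lists with at least 5 tested genes were tested with camera at a correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists. Fry values are those of its directional test unless the mixed test is named. The score of a list in a tumour is the median over its genes of log2 CPM (prior count 1) minus the off-dox mean. Genes named in the text follow a rule fixed in advance. It takes 9 genes of the malic enzyme axis always; up to 10 higher and 10 lower with the largest log2 fold change among called genes with a mean log2 CPM of at least 1 and groups that do not overlap; and up to 4 members with the smallest p of each list described. Genes of the Y chromosome, XIST and clone names were passed over. Some genes that the rule takes are not reported here. Which lists without a call had members named was decided after the results were seen.

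The test was checked on simulated counts for the 21308 genes, with the real means and library sizes. The genes made to change were drawn from those with a mean CPM over 2. It recovered 25.4% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 98.5% of those changed 4-fold, so most smaller changes are missed. Of 139 calls in that simulation 16 were false, 11.5%, which is above the nominal 5%. The simulated list shift was called, and 1 of the other lists was called falsely. The simulated genes varied independently, while the estimated correlation in the real lists reached 0.92 for cytosolic ribosomal proteins and 0.97 for muscle. This check therefore cannot give camera's rate of false calls on the real lists.

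The alternatives tried were other scalings (DESeq2 size factors and upper quartile), no or a stricter low-count filter, robust quasi-likelihood fitting, DESeq2 1.42.0, limma voom, a replicate block, an adjusted p threshold of 0.1, a test against a 1.5-fold change, fits without host cell type genes, and fits without each tumour in turn. With 1 on-dox tumour left, that tumour is assumed to vary like the off-dox tumours. Words of 7 bases in 3' UTRs were scanned with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 after the gene results were seen, and words of 8 bases were looked at too. The scan took 10553 genes with a mean log2 CPM of at least 2 and a 3' UTR of at least 50 bases, and used the longest annotated 3' UTR per gene. It tested the rank of log2 fold changes divided by their SE, after adjustment for UTR length and GC content. The scan was repeated 12 times on 1 on-dox and 2 off-dox tumours, and the word with the lowest score was then scored in the other 3 tumours. These scans, and those of each on-dox tumour alone, ranked differences of log2 of CPM plus 0.5, with the same adjustment. Their scores are therefore on another measure than those of the main scan.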

Results

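Gene expression was measured by RNA sequencing in 6 subcutaneous tumours grown in nude mice from PATU, a cell line of pancreatic ductal adenocarcinoma. The cells carried a doxycycline-inducible short hairpin against ME3, the mitochondrial NADP-dependent malic enzyme. The 4 tumours off doxycycline kept the hairpin uninduced, and the 2 tumours on doxycycline were treated to knock ME3 down. The total count was 26885699, 24812589, 23855338 and 26108647 in off-dox tumours 1 to 4, and 24529707 and 25731887 in on-dox tumours 1 and 2. The comparison asks what the induction of the hairpin does to the tumours' transcripts. The study concerns deletion of malic enzyme 2 and its lethal consequences in pancreas cancer. The labels name separate tumours of each group, so the p-values measure the spread between tumours of one cell line.

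ME3 (ENSG00000151376) was at 41.2 ± 3.39 CPM (counts scaled to library size; SD, n = 4) off dox and at 30.9 ± 3.39 CPM (SD, n = 2) on dox. Both on-dox tumours lay below all 4 off-dox tumours, which ranged from 37.9 to 44.2 CPM. The log2 fold change of ME3 was -0.41 (SE 0.12), with a 95% interval from -0.68 to -0.15. This difference did not pass correction over all genes (adjusted p = 0.148). The two-sided exact permutation test over the 15 splits of the 6 tumours gave p = 0.0667, the smallest that this design allows. BCAT2 (ENSG00000105552), the mitochondrial branched-chain aminotransferase, fell from 24.7 ± 1.95 to 14.9 ± 0.974 CPM (SD, n = 4 and n = 2), a log2 fold change of -0.73 (SE 0.13, adjusted p = 0.0314). The BCAT2 call was lost when any 1 tumour other than on-dox tumour 2 was left out, with adjusted p from 0.0533 to 0.126 and log2 fold changes from -0.78 to -0.67.

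The other genes of this axis did not pass the test. ME1, the cytosolic malic enzyme, was at 43.3 ± 6.84 CPM off dox and 44.5 ± 1.62 CPM on dox (log2 fold change 0.04, SE 0.14, adjusted p = 0.932). ME2, the gene whose deletion gives the series its title, was at 20.2 ± 0.962 and 24.5 ± 5.95 CPM (log2 fold change 0.28, SE 0.15, adjusted p = 0.426). This was 0.007 without on-dox tumour 1, at 28.67 CPM, and 0.501 without on-dox tumour 2, at 20.26 CPM. Its transcript was counted in all 6 tumours. The labels do not say whether PATU carries that deletion, and mouse reads can be part of these counts. SMAD4, a tumour suppressor often deleted in this cancer, was at 3.52 ± 1.14 and 2.26 ± 0.296 CPM (adjusted p = 0.403). Its neighbour ELAC1 was at 9.49 ± 0.944 and 13.6 ± 4.78 CPM (adjusted p = 0.28; log2 fold change 0.102 without on-dox tumour 1 and 0.831 without on-dox tumour 2). The sterol regulatory factor SREBF1 was at 140 ± 7.29 CPM off dox and 166 ± 2.81 CPM on dox (log2 fold change 0.25, adjusted p = 0.236). Both on-dox tumours, at 163.9 and 167.8 CPM, lay above the off-dox range of 132.6 to 146.8 CPM. The exact permutation test gave p = 0.0667 for SREBF1 and for BCAT2, the same as for ME3. SREBF2 was at 201 ± 24.1 and 211 ± 17.8 CPM (log2 fold change 0.07, adjusted p = 0.857). BCAT1 had 3 counts over the 6 tumours and was not tested.

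**Figure D1:**
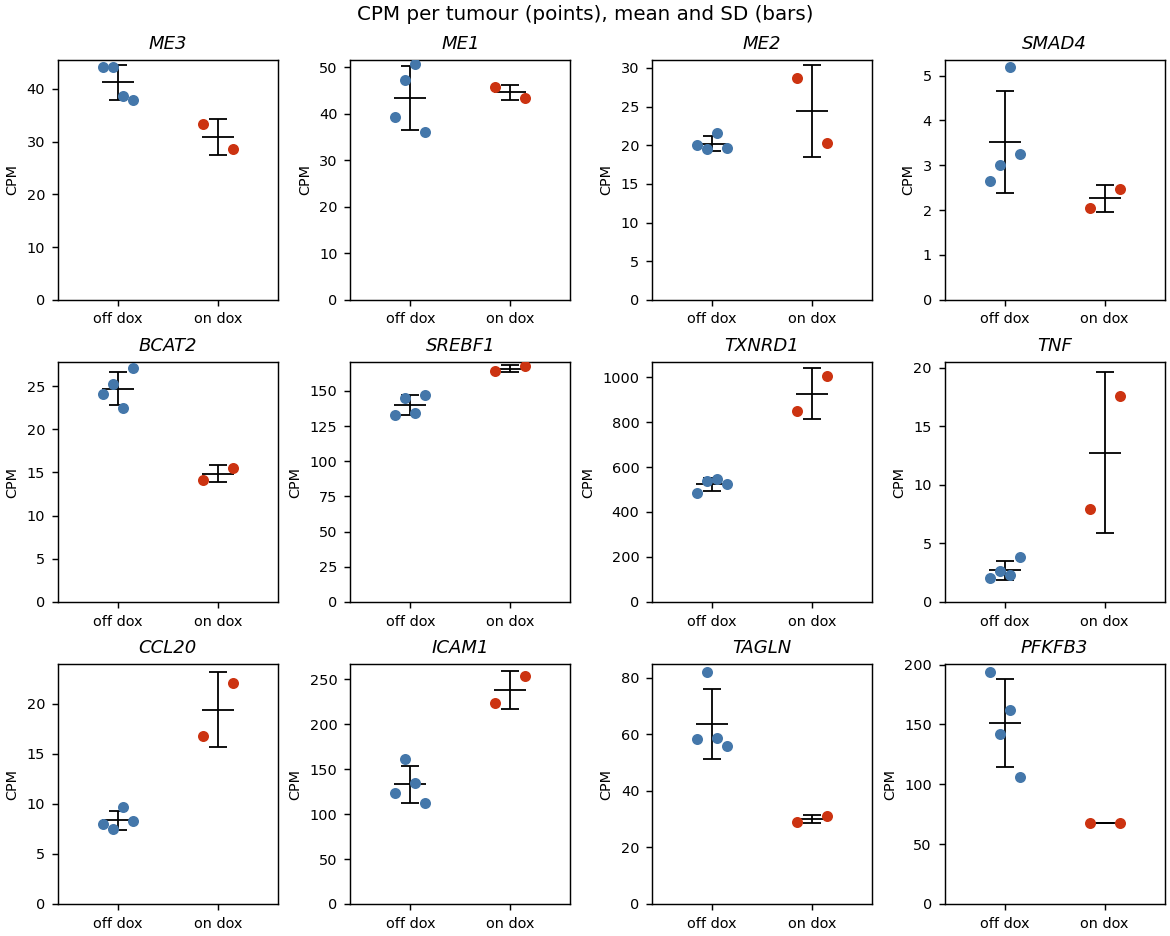
CPM of 12 genes in each tumour, with 4 points off dox, 2 points on dox and bars for the mean and SD; each vertical axis starts at 0. The on-dox points of ME3 lie at 33.3 and 28.5 CPM, below the off-dox points, and those of ME1 at 45.7 and 43.4 CPM, within them.

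The largest rise on dox among genes eligible for naming was in OLR1, the scavenger receptor for oxidised low-density lipoprotein, which went from 0.284 ± 0.146 CPM (SD, n = 4) to 6.27 ± 2.3 CPM (SD, n = 2), 21.6-fold. The cytokine gene TNF rose 4.71-fold, from 2.7 ± 0.8 to 12.7 ± 6.84 CPM (adjusted p = 0.0136; log2 fold change 1.544 without on-dox tumour 2, 2.703 without on-dox tumour 1), and the lysosomal protease gene CTSS rose 3.31-fold. The calcium-binding protein gene S100A4 rose from 64.8 ± 5.16 to 205 ± 106 CPM (log2 fold change 1.001 without on-dox tumour 2, 2.113 without on-dox tumour 1). PDLIM3, which encodes an actin-associated PDZ and LIM domain protein, fell from 6.17 ± 1.32 to 0.771 ± 0.116 CPM, a log2 fold change of -2.99 (SE 0.31, adjusted p = 0.00329). The doublecortin-like kinase gene DCLK1 fell from 279 ± 68.6 to 76.7 ± 6.99 CPM, a log2 fold change of -1.86 (SE 0.21, adjusted p = 0.00455).

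Among genes eligible for naming, the other large rises were in PADI2, a peptidylarginine deiminase gene (3.29-fold), the interferon-induced gene IFI44L (3.1-fold), FRG1B (3.07-fold), IGDCC4 (3.06-fold), NPY4R (2.93-fold) and C1QTNF1 (2.88-fold). CCL2, with a mean log2 CPM of 0.83 below the cut for naming, rose 7.13-fold. FRG1B and NPY4R have near-identical copies elsewhere in the genome, so their counts are uncertain. The other large falls among genes eligible for naming, as log2 fold changes, were in DTNA (-2.81), DPYSL3 (-2.40), the striated muscle kinase gene SPEG (-2.07), FREM2 (-2.02), the carbonic anhydrase gene CA2 (-1.99), the BMP antagonist gene CHRDL1 (-1.84), TENM2 (-1.82) and FAM83B (-1.80). That of DPYSL3 was -3.576 without on-dox tumour 2 and -1.746 without on-dox tumour 1, and it was called in 1 of the 6 fits without a tumour. In all, 225 of 21308 genes changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 99 higher and 126 lower on dox. Of these, 45 were at least 2-fold higher and 58 at least 2-fold lower. The count was 72 without on-dox tumour 1, 562 without on-dox tumour 2, and 96, 80, 83 and 133 without off-dox tumours 1 to 4. Each of the 225 log2 fold changes kept its sign in those fits. In all 225 the CPM of the 2 groups did not overlap, so leaving out 1 tumour could hardly turn a sign. The kept signs are therefore no test of stability. Of the called genes named here, OLR1, TNF, CTSS, PADI2, FRG1B, PDLIM3, DCLK1 and CCL2 stayed called under each other scaling, filter, tool and block and with any 1 tumour left out. The other called genes that the naming rule takes and that are reported here lost the call in at least 1 of those fits. Called genes named outside the rule were not followed over those fits. Against a 1.5-fold change only OLR1, FRG1B and PDLIM3 were called.

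**Figure D2:**
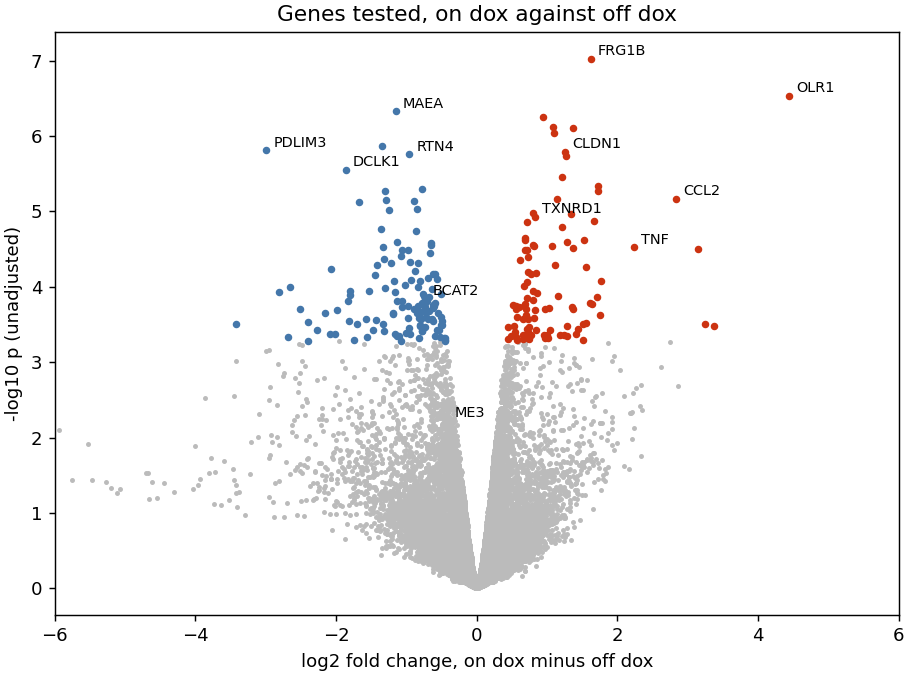
Log2 fold change, on dox minus off dox, against -log10 of the unadjusted p of edgeR's quasi-likelihood test, with 1 point for each of 21274 genes, red for higher and blue for lower on dox at an adjusted p under 0.05. OLR1 at 4.43 and PDLIM3 at -2.99 lie apart, ME3 at -0.41 lies among the grey points, and 7 genes beyond a log2 fold change of 6 in size and those of the Y chromosome and the XIST locus are not drawn.

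The inflammatory and interferon lists were called higher on dox by camera, with few genes passing singly, but not with an estimated correlation or fry. Of 21 tested genes of the NF-kB and inflammatory cytokine list, 4 rose and 17 did not pass over all genes. When adjusted over the list alone, 9 were higher and 1 lower. The chemokine gene CCL2 rose from 0.555 ± 0.215 to 3.99 ± 0.378 CPM (SD, n = 4 and n = 2), CCL20 rose 2.32-fold, TNF rose as given above, and the adhesion molecule gene ICAM1 rose from 133 ± 21 to 238 ± 21.2 CPM. The list's median log2 fold change was 0.33 (camera adjusted p = 6.9e-09; adjusted p = 0.324 with an estimated correlation and 0.121 with fry). Both on-dox tumours, at 0.43 and 0.44 relative to the off-dox mean, lay above the off-dox maximum of 0.12.

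Of 33 interferon response genes, 4 rose over all genes and 18 when adjusted over the list alone, and 32 had a log2 fold change above 0. These 4 were IFI44L, the transcription factor gene IRF1 (1.47-fold), XAF1 (2.83-fold) and the antiviral tetherin gene BST2 (2.71-fold). The list's median was 0.43 (camera adjusted p = 6.6e-19; adjusted p = 0.65 with an estimated correlation and 0.416 with fry). The off-dox tumours themselves ranged from -0.30 to 0.29. On-dox tumours 1 and 2 were at 0.328 and 0.536, the former near off-dox tumour 2 at 0.285. The list of MHC class I presentation had a median of 0.37, with all 15 genes above 0 (camera adjusted p = 2.63e-07; adjusted p = 0.65 with an estimated correlation). In it the peptide transporter gene TAP2 rose 1.46-fold, and 4 genes were higher when adjusted over the list alone. ERAP1 (log2 fold change 0.41, adjusted p = 0.0727), TAPBP (0.37, adjusted p = 0.127) and TAP1 (0.43, adjusted p = 0.138) did not pass over all genes. That of TAP1 was 0.229 without on-dox tumour 2 and 0.603 without on-dox tumour 1. Without on-dox tumour 2 the class I list had a median of 0.17 and lost its call (adjusted p = 0.0762). The host myeloid list, 9 tested genes, had a median of 0.10 and none changed singly (camera adjusted p = 0.263; adjusted p = 0.813 with an estimated correlation of 0.42). Camera at the preset correlation of 0.01 called it higher without off-dox tumour 3 (median 0.391, adjusted p = 0.0167), with a replicate block (0.7, adjusted p = 0.00487) and with no low-count filter (0.442, adjusted p = 0.0337).

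The glycolysis and hypoxia lists were called lower on dox by camera (adjusted p = 1.07e-09 and 1.63e-07), with few genes passing singly. Neither was called with an estimated correlation (adjusted p = 0.65 for each) or with fry (0.416 for each). All 19 tested glycolysis genes had a log2 fold change below 0, with a median of -0.31, and of -0.164 without on-dox tumour 1, where camera at the preset correlation still called it (adjusted p = 0.000549). The list's score was -0.43 and -0.163 in on-dox tumours 1 and 2, the latter near off-dox tumour 4 at -0.121. The lactate exporter gene SLC16A3 fell from 42.5 ± 1.87 to 23.2 ± 3.13 CPM (SD, n = 4 and n = 2; adjusted p = 0.0118). In this list 6 genes were lower when adjusted over the list alone. ENO2 had a log2 fold change of -0.93 (adjusted p = 0.0989), ALDOC of -0.85 (adjusted p = 0.105; -0.528 without on-dox tumour 1) and HK2 of -0.63 (adjusted p = 0.11), none past the threshold. Of 23 hypoxia response genes, 22 lay below 0, with a median of -0.30 (-0.49 without off-dox tumour 4, -0.195 without off-dox tumour 1); 2 fell over all genes and 8 when adjusted over the list alone. PFKFB3, which encodes an activator of glycolytic flux, fell from 151 ± 36.8 to 67.6 ± 0.177 CPM. The vasodilator peptide gene ADM fell from 122 ± 8.46 to 85.7 ± 4.21 CPM. VEGFA had a log2 fold change of -0.57 (adjusted p = 0.0794) and PFKFB4 of -0.95 (adjusted p = 0.0869). Off-dox tumour 4, at -0.33 for the hypoxia list, reached the values of both on-dox tumours, at -0.33 each. Off-dox tumour 1 was at 0.33.

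Some markers of epithelial cells and of a mesenchymal state changed, but neither list as a set separated the groups. The epithelial score was 0.081 and 0.145 in on-dox tumours 1 and 2, within the off-dox range of -0.115 to 0.231. The mesenchymal score was -0.162 and -0.111, within the off-dox range of -0.178 to 0.076. Of 15 tested epithelial and ductal markers, the tight junction gene CLDN1 rose from 162 ± 22.8 to 385 ± 53.1 CPM. EPCAM (log2 fold change 0.39, adjusted p = 0.168) and KRT8 (-0.36, adjusted p = 0.198) did not pass over all genes. In the list 4 genes were higher and 1 lower when adjusted over the list alone. The list's median was 0.05 (camera adjusted p = 0.0165; adjusted p = 0.65 with an estimated correlation). The epithelial call was lost without off-dox tumour 4 (median 0.061, adjusted p = 0.113) or on-dox tumour 2 (0.014, adjusted p = 0.0625). It was also lost with the replicate block (0.066, adjusted p = 0.0935) and limma voom (0.112, adjusted p = 0.116). In the list of mesenchymal genes and TGF-beta or YAP targets, 2 of 22 genes were lower when adjusted over the list alone. AXL was at -0.42 (adjusted p = 0.101), FN1 at -0.43 (adjusted p = 0.219) and CYR61 at 0.55 (adjusted p = 0.254; 0.198 without on-dox tumour 1 and 0.826 without on-dox tumour 2). Its median was -0.21 (camera adjusted p = 0.0256; adjusted p = 0.65 with an estimated correlation). The call was lost without off-dox tumour 2 (median -0.124, adjusted p = 0.0736) or on-dox tumour 1 (-0.179, adjusted p = 0.125).

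Host tissue markers varied between tumours. In the fibroblast and matrix list, TAGLN, an actin-binding protein gene also expressed by carcinoma cells, fell from 63.7 ± 12.3 to 30.1 ± 1.37 CPM. It was the 1 of 20 genes called, over all genes and when adjusted over the list alone. DCN, COL5A1 and SPARC had log2 fold changes of -2.06, -0.74 and -0.95 (adjusted p = 0.235, 0.283 and 0.287). With 1 tumour left out they ranged from -3.577 to -1.323 for DCN, -0.939 to -0.564 for COL5A1 and -1.516 to -0.54 for SPARC. The list's median was -0.30 (camera adjusted p = 0.000884; adjusted p = 0.741 with an estimated correlation), and -0.13 without on-dox tumour 1 (adjusted p = 0.569). Skeletal muscle transcripts were high in off-dox tumour 4, where MYLPF was at 10.7 CPM against 0.0769 to 0.446 CPM in the other off-dox tumours, TNNC2 at 17.7 CPM and DES at 27.6 CPM. MYL1 was at 15.4 CPM there, at 1.541 CPM in off-dox tumour 2 and had no counts in the other off-dox or either on-dox tumours. None of the 14 muscle genes changed singly. Camera called the list lower (median -4.43, adjusted p = 0.00918; adjusted p = 0.813 with an estimated correlation). The muscle call was lost without off-dox tumour 4 (median -1.21, adjusted p = 0.701), off-dox tumour 2 (-4.274, adjusted p = 0.0513) or on-dox tumour 1 (-3.6, adjusted p = 0.164). It was also lost with robust quasi-likelihood (-4.43, adjusted p = 0.111) and limma voom (-1.438, adjusted p = 0.116). Endothelial (median -0.17, camera adjusted p = 0.408), adipocyte (-0.98, adjusted p = 0.353) and squamous markers (-0.36, adjusted p = 0.342; 1 gene higher and 2 lower when adjusted over the list alone) were not called. With 1 tumour left out, their medians ranged from -0.323 to -0.023, -1.303 to -0.109 and -0.513 to -0.28. Only 2 erythroid genes were tested, too few for the list test.

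Mitochondrial transcripts separated the on-dox tumours from each other. The mRNAs of the mitochondrial genome had a median log2 fold change of 1.01, with 0 of 13 called over all genes and 11 higher when adjusted over the list alone (camera adjusted p = 1.07e-09; adjusted p = 0.65 with an estimated correlation). MT-ND5 was at 421 CPM in on-dox tumour 1, at 144 CPM in on-dox tumour 2 and at 77.7 to 129 CPM off dox (adjusted p = 0.068). MT-CYB was at 361, 138 and 92.3 to 133 CPM (adjusted p = 0.0913). In on-dox tumour 1 these mRNAs took 0.529% of counts, against 0.222% to 0.276% in the other 5 tumours. The nuclear RNAs MALAT1 and NEAT1 took 4.08%, against 1.48% to 2.33%. Without that tumour the list had a median of 0.13 and was not called (adjusted p = 0.143).

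Genes of nuclear-encoded mitochondrial proteins, ribosomes, sterol synthesis and mitosis were lower by camera, mainly in the same on-dox tumour 1. The medians were -0.11 for 50 respiratory chain genes, -0.10 for 42 mitochondrial ribosome genes and -0.27 for 40 cytosolic ribosomal protein genes (camera adjusted p = 0.0244, 0.00918 and 6.9e-09; adjusted p = 0.813, 0.813 and 0.761 with an estimated correlation). No gene of these lists was called over all genes or when adjusted over the list alone. UQCRFS1 (log2 fold change -0.56, adjusted p = 0.0896), MRPL1 (-0.41, adjusted p = 0.212) and RPL13 (-0.51, adjusted p = 0.162) had the smallest p in each. Their log2 fold changes were -0.309, -0.284 and -0.308 without on-dox tumour 1. Without on-dox tumour 1 these medians were 0.16, 0.083 and 0.005, and the respiratory chain list was then called higher (adjusted p = 0.000267). The respiratory chain call was also lost without off-dox tumours 1 or 4 (medians -0.064 and -0.081, adjusted p = 0.13 and 0.108) and with DESeq2 (-0.102, adjusted p = 0.0789). The mitochondrial ribosome call was lost without off-dox tumour 4 (-0.08, adjusted p = 0.0517).

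Cholesterol synthesis and uptake genes had a median of -0.25 and 20 of 24 lay below 0 (camera adjusted p = 7.63e-05; adjusted p = 0.741 with an estimated correlation). None was called over all genes, and 1 was higher and 3 lower when adjusted over the list alone. DHCR7, of the last steps of the pathway, had a log2 fold change of -0.46 (adjusted p = 0.0729). Of 27 ATF4 targets, DDIT4, an inhibitor of mTORC1 signalling, fell from 51.5 ± 6.02 to 31.9 ± 2.49 CPM. In that list 2 genes were lower when adjusted over the list alone (median -0.12, camera adjusted p = 0.0362; adjusted p = 0.761 with an estimated correlation). Of 14 heat shock chaperone genes, HSPB1 fell from 9.65 ± 1.39 to 4.23 ± 0.946 CPM, the 1 gene also called when adjusted over the list alone (median -0.21, camera adjusted p = 0.000413; adjusted p = 0.65 with an estimated correlation). None of 30 mitotic genes (median -0.19) and none of 9 histone genes (median -0.40) passed, over all genes or when adjusted over the list alone. The histone list holds non-polyadenylated mRNAs and was written as a measure of RNA quality. Camera called both lists lower (adjusted p = 0.000884 and 0.000801; adjusted p = 0.771 and 0.65 with an estimated correlation). The mitotic list held CDC20 at -0.40 (adjusted p = 0.121) and, in the other direction, MKI67 at 0.48 (adjusted p = 0.2; 0.131 without on-dox tumour 1 and 0.76 without on-dox tumour 2). Without on-dox tumour 1 all 5 of these lists lost the call. The medians were then -0.065 for sterol, -0.003 for ATF4, -0.04 for mitosis and -0.094 for histones (adjusted p = 0.327, 0.972, 0.546 and 0.711). The heat shock median stayed at -0.211 (adjusted p = 0.0866). The ATF4 call was also lost without off-dox tumours 1 or 2 (medians -0.09 and -0.132, adjusted p = 0.108 and 0.0809).

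Branched-chain amino acid breakdown as a list was not called (25 genes, median 0.05, camera adjusted p = 0.873). BCAT2 was the 1 gene that fell, over all genes and when adjusted over the list alone, while ACADSB (log2 fold change 0.45, adjusted p = 0.182) and MCCC2 (0.29, adjusted p = 0.2) lay above 0. In the NRF2 target list (26 genes, median -0.10, camera adjusted p = 0.387), the thioredoxin reductase gene TXNRD1 rose from 522 ± 27.4 to 927 ± 112 CPM (adjusted p = 0.00903). By contrast HMOX1 was at -0.49 (adjusted p = 0.0705) and TKT at -0.35 (adjusted p = 0.193). The value of TKT was -0.203 without on-dox tumour 1 and -0.509 without on-dox tumour 2. In this list 1 gene was higher and 1 lower when adjusted over the list alone. In the list of antioxidant enzymes and NADPH sources (27 genes, median -0.019, camera adjusted p = 0.511), none passed over all genes and 1 was lower when adjusted over the list alone. The cytosolic isocitrate dehydrogenase gene IDH1, at -0.53, missed the threshold (adjusted p = 0.0519).

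Fatty acid synthesis (18 genes, median -0.07, camera adjusted p = 0.577) and nucleotide synthesis (22 genes, median -0.038, adjusted p = 0.577) held no gene that passed, over all genes or when adjusted over the list alone. SCD was at 0.27 (adjusted p = 0.237) and PRPS2 at -0.33 (adjusted p = 0.237). In the apoptosis list the median was -0.048, the mean 0 and the camera direction up (23 genes, adjusted p = 0.576). BIRC3, an inhibitor of apoptosis and NF-kB target, was at 0.69 (adjusted p = 0.0508) and the 1 gene called when adjusted over the list alone. Camera did not call DNA replication (median 0.029, adjusted p = 0.577), the tricarboxylic acid cycle (-0.036, adjusted p = 0.353), or glutamine and glutamate metabolism (-0.062, adjusted p = 0.765). It did not call autophagy and lysosome (0.049, adjusted p = 0.577), the unfolded protein response (0.075, adjusted p = 0.263) or p53 targets (-0.14, adjusted p = 0.351). Nor were immediate early genes (-0.21, adjusted p = 0.0695) or abundant small and nuclear RNAs (-0.20, adjusted p = 0.765) called. The immediate early median was -0.293 without on-dox tumour 1 and -0.104 without on-dox tumour 2. None of the genes of these 8 lists passed over all genes. When adjusted over the list alone, 1 gene of the tricarboxylic acid cycle and 2 immediate early genes were lower.

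Over the 36 lists tested, camera with a preset correlation of 0.01 called 18, 5 higher and 13 lower. With an estimated correlation it called 0, with 1 list at an unadjusted p under 0.05, the NF-kB list. Fry's directional test called 0, with 2 at an unadjusted p under 0.05, the immediate early (lowest adjusted p 0.11) and NF-kB lists. Fry's mixed test, which takes changes in either direction, did pass 0.05 for some lists. Its adjusted p was 0.000137 for NRF2 targets and 0.000613 for the NF-kB list, but 0.0735 for glycolysis and 0.0995 for hypoxia. Without on-dox tumour 1, camera called 9 lists, among them the NF-kB, interferon, class I, epithelial, glycolysis and hypoxia lists in the directions given here. The other 3 were the respiratory chain, unfolded protein response and DNA replication lists, called higher.

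**Figure D3:**
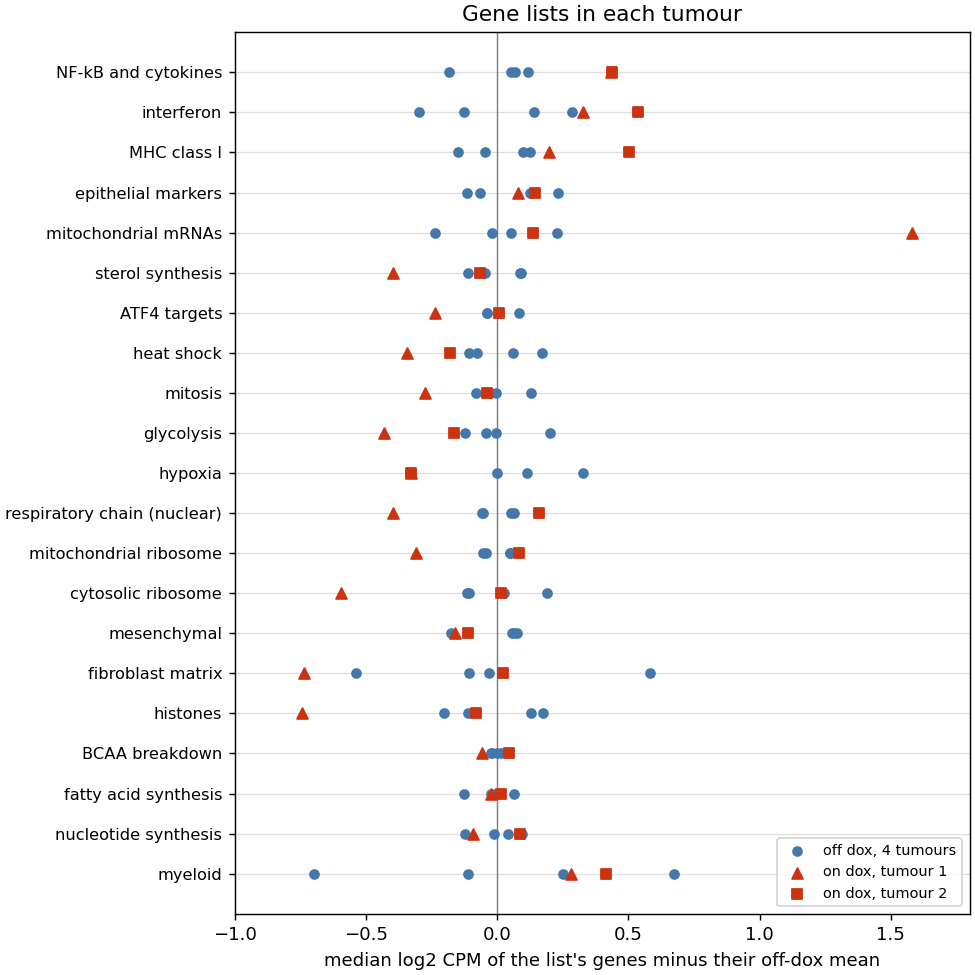
Median log2 CPM of the genes of 21 lists in each tumour, minus their off-dox mean, with blue points for the 4 off-dox tumours, a red triangle for on-dox tumour 1 and a red square for on-dox tumour 2. The on-dox tumours lie together at 0.43 and 0.44 for the NF-kB list and far apart at 1.58 and 0.14 for the mitochondrial mRNAs.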

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

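Each of these values was singled out because 1 of the 4 off-dox tumours lay far from the other 3, by the gap to its nearest neighbour divided by the group's range; which genes of lists without a call entered this check was decided after the results were seen. Of 163 items tested, 14 stood out, where chance gives about 1 in 20, or 8.2. No explanation was tested for any of them.

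In off-dox tumour 4, 3 skeletal muscle genes stood above the others: MYLPF at 10.7 CPM against at most 0.446 (gap ratio 0.965), MYL1 at 15.4 CPM against at most 1.54 (0.900) and TNNC2 at 17.7 CPM against at most 1.87 (0.899). The same tumour was lowest for the mesenchymal list, at -0.18 against 0.055 to 0.076 (0.917), and highest for S100A4, at 72.5 CPM against 61.8 to 62.8 (0.907).

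Off-dox tumour 3 was lowest for the glutamine and glutamate list, at -0.098 against 0.026 to 0.04 (0.899), for the sterol gene MVD, at 61 CPM against 68.8 to 69.3 (0.940), for the mitotic kinase gene PLK1, at 58.3 CPM against 64.2 to 65.4 (0.832), and for ADM, at 109.7 CPM against 124.8 to 127.8 (0.834). It was highest for the mitochondrial ribosome gene MRPL1, at 21.5 CPM against 18.2 to 18.6 (0.878).

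Off-dox tumour 1 was highest for the stress response gene TRIB3, at 35.6 CPM against 25.2 to 26.8 (0.844), and for the heat shock gene HSPA1B, at 134.6 CPM against 64.2 to 73.9 (0.863); HSPA1B shares nearly all of its sequence with HSPA1A, so its count is uncertain. Off-dox tumour 2 was highest for TAGLN, at 82.1 CPM against 55.9 to 58.6 (0.898), and for the mitochondrial dehydrogenase gene HSD17B10, at 47.3 CPM against 34.5 to 36.4 (0.851). The fall of TAGLN on dox lost its call without on-dox tumour 1 (adjusted p = 0.094), with log2 fold changes from -1.14 to -0.94 when 1 tumour was left out.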

How the results depend on the processing

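The fits without genes holding the 3' UTR words were chosen after seeing the data; the others were planned. The count of 225 genes (99 higher, 126 lower) was 770 (310, 460) with no low-count filter, 697 (297, 400) with DESeq2, 533 (244, 289) at an adjusted p under 0.1, and 3 (2, 1) when tested against a 1.5-fold change, namely OLR1, FRG1B and PDLIM3; looser thresholds and more tested genes account for part of this by construction, and the cause was otherwise not tested. It stayed within 1.5 times under the other scalings (216 and 228), the strict filter (241), robust fitting (304), limma voom (184, with 51.1% higher), without host cell type genes (246) and without genes holding the words (191). The replicate block gave 53 genes (23 higher, 30 lower), 36 of them among the 225; the labels share only numbers 1 and 2, and the deviations of same-numbered tumours had a correlation of -0.02 across genes, so the numbers are not read as pairs. Leaving out 1 tumour gave 72 to 562 genes, 39 to 231 higher and 33 to 331 lower, with fewer samples in each fit. ME3 was called in none of the 15 alternative fits, with log2 fold changes from -0.53 to -0.31 and adjusted p from 0.0701 to 0.491. The number of lists called was 0 with an estimated correlation, 0 with fry, and 9 to 21 with 1 tumour left out. Medians that changed sign or direction were those of autophagy (0.017), adipocyte (0.286) and apoptosis genes (0.001) under the block and endothelial genes with DESeq2 (-0.081); the cause was not tested. With 1 tumour left out, the ranges that crossed 0 or changed direction were -0.039 to 0.124 for ME1, -0.021 to 0.145 for SREBF2, and for list medians -0.621 to 0.084 for small and nuclear RNAs, -0.068 to 0.045 for branched-chain amino acids, -0.118 to 0.126 for DNA replication, -0.099 to 0.083 for nucleotides, -0.216 to 0.038 for glutamine, -0.241 to 0.06 for NRF2 targets, -0.277 to 0.099 for antioxidants, -0.339 to 0.055 for p53 targets, -0.405 to 0.159 for the respiratory chain, -0.316 to 0.083 for the mitochondrial ribosome, -0.193 to 0.07 for the tricarboxylic acid cycle, -0.607 to 0.005 for the cytosolic ribosome, -0.099 to 0.16 for the unfolded protein response, -0.107 to 0.012 for apoptosis and -0.026 to 0.106 for autophagy.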

Other observations

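The tests of this part were chosen after the results were seen, except for 3 whose bounds were written before their values were known: the share of genes holding the 3' UTR word, its score in each on-dox tumour, and its count in BCAT2. Besides TAGLN and PDLIM3, other actin-binding and contractile genes were among those that fell: SMTN (log2 fold change -1.25), FHL2 (-1.01), FLNC (-0.94), TPM2 (-0.75), PDLIM7 (-0.67) and PARVA (-0.65). With TAGLN and PDLIM3 these are 8 of 39 tested genes of a list written after the called genes were known, so their share tests nothing. None of the list was called higher, and 28 of the 39 had a log2 fold change below 0. Others, such as PDLIM1 at 0.32, lay above 0. The list's median was -0.28, and its score was -0.31 and -0.20 in the on-dox tumours against -0.054 to 0.094 off dox. In the host lists, 19 of 20 fibroblast genes (median -0.30; 2 genes shared with the actin list, TAGLN and ACTA2) and 14 of 14 muscle genes (median -4.43) had a log2 fold change below 0. On-dox tumour 2 was at 0.021 for the fibroblast list, and both on-dox tumours, at -2.599 and -0.947, lay within the off-dox range of -3.224 to 4.343 for the muscle list. Neither list was called with an estimated correlation (adjusted p = 0.741 and 0.813). Whether tumour or host cells account for the falls was not tested.

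Several called genes outside the naming rule were picked after their values were seen. PTX3, the long pentraxin gene, rose from 95 ± 7.09 to 201.5 ± 27.6 CPM (SD, n = 4 and n = 2), IRAK2, a kinase of interleukin-1 receptor signalling, rose 1.76-fold, and CSF1, the macrophage growth factor gene, rose 1.59-fold. CPT1A, the carnitine palmitoyltransferase gene of fatty acid oxidation, rose 1.44-fold. The ubiquitin ligase subunit gene MAEA fell from 76.8 ± 5.9 to 34.6 ± 1.26 CPM, the reticulon gene RTN4 fell by 0.96 on the log2 scale, and the receptor gene FGFR1 fell by 0.89.

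The grouping itself gave 225 genes, and the highest count among the other 14 of the 15 splits of the 6 tumours into 4 and 2 was 5; 1 split gave as many as 225, the real one. The 15 splits are too few for a share under 0.05.

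Genes holding either of 2 overlapping words in their 3' UTRs ranked lower on dox, by a small shift. The 310 scanned genes with such a word had a median log2 fold change of -0.073, against 0 for those without. Of 108 scanned genes called lower, 91 held neither word. Of 16165 words of 7 bases, TACCGTA had the lowest rank score (z = -7.74) and ACCGTAA, shifted by 1 base, the next (-7.16). In 12 of 12 scans of 1 on-dox and 2 off-dox tumours the lowest was 1 of them, at -5.06 to -7.53 in the 3 tumours held out. These scans use each split of the tumours in both directions and share the same 2 on-dox tumours, so they are not 12 replications. The lowest score in 100 shuffles of values over genes was -5.04. These shuffles take genes as independent, so they cannot tell whether co-regulated genes vary this much between tumours by chance. At the other end TATTTAT, in 3900 genes, scored 5.57. TACCGTA in each on-dox tumour alone gave -5.54 or lower and ACCGTAA -5.46 or lower, which argues against a single library. The 178 words of the same bases with a CG had a median of -0.1 (SD 1.11), which argues against base composition alone. The lowest of them, CCGTAAT at -4.9 and overlapping ACCGTAA, did not clear the first bound set for this test. The median was used only after that. Other words with a CG, such as CGAGGCA (-4.64) and GTACGTA (-4.01), also scored low. Off-target pairing of the hairpin's guide strand through its seed stays open. Both words occur in the coding region of ME3, overlapping as TACCGTAA. Of all single words, 19.8% occur in some part of an ME3 transcript, coding or not, so that share is no rate for this overlapping match. The labels give 0 hairpin sequences. The words were held by 17 of 108 genes called lower against 293 of 10366 not called (2.83%), a ratio of 5.56. This ratio is no test, since the words were chosen on the same fold changes. BCAT2 holds 0 of these words in its longest annotated 3' UTR, of 488 bases, which argues against the word in that 3' UTR as the reason for its fall. The rest of the BCAT2 transcripts was not searched. Among other genes named above, DCLK1 and RTN4, both called lower, hold 1 of these words each. DPYSL3, also called lower, and COL5A1 and SMAD4, not called, hold at least 1. For these genes too, off-target pairing stays open.

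On-dox tumour 1 was high in mitochondrial mRNAs, MALAT1 and NEAT1. Its score for the mitochondrial list was 1.58, that of on-dox tumour 2 was 0.138, and off-dox tumours reached 0.228. Its total of 24.53 M counts lies within the range of the other tumours, which argues against library size. The make-up of its RNA also differed. Small structured RNAs took 4.564% of its counts, against 6.114% to 7.719% in the other tumours, and RN7SK among them 2.131%, against 3.27% to 3.67%. Whether the tumour, its response to doxycycline or the preparation of its RNA differed stays open.

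CCL2, TNF, CCL20 and ICAM1 rose on dox, and more host myeloid cells may raise such genes. The 9 myeloid markers had a mean log2 fold change of 0.24, with an upper 95% limit of 0.98 after widening for their correlation of 0.42, against 1.21 for the smallest change of CCL2, TNF and CCL20 and 0.84 for ICAM1. This interval takes the genes, not the tumours, as replicates. The myeloid list's score ranged from -0.698 to 0.673 among the off-dox tumours, and was 0.28 and 0.414 in on-dox tumours 1 and 2. The upper limit was not under the smallest change of CCL2, TNF and CCL20 in 3 of 15 fits. It was 1.51 against 1.32 with the replicate block, 1.49 against 1.40 without on-dox tumour 1 and 1.34 against 1.29 without off-dox tumour 3. The list was called higher in some fits (median 0.7, camera adjusted p = 0.00487 with the block, at a preset correlation of 0.01), so myeloid cells stay open. The most abundant markers, CYBB, CSF1R and PTPRC, were at 19.6, 12.7 and 9.5 CPM off dox and 24.9, 13.6 and 9.83 CPM on dox. Doxycycline or hairpin expression and any effect of lower ME3, itself not called on dox, cannot be told apart, since 0 tumours carried a control hairpin.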
